A study of Mus musculus with 19 samples.

How the data were processed

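Placentas of mouse embryos were profiled by poly(A) RNA sequencing with strand information. The authors trimmed the reads with cutadapt 1.8, aligned them to mm10 with TopHat2 2.1.1 and counted fragments per gene with Cuffdiff 2.2.1. The gene annotation they used is not stated. The deposited tables give the raw fragments of each gene in each library, and these values are expected counts: 98.8% of the cells are whole numbers, and the fractional cells, found in 358 genes, hold 0.965% of all fragments. The raw fragments were rounded to whole numbers and used in every test. The scaled fragments, the normalised values and the difference tests in the deposited tables were not used here.

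The tables hold 23361 genes, of which 3175 have 0 fragments in all 19 libraries. Females and males stand in separate tables, and the 4 placentas of the Mcm4 C3/C3 group stand again in a table of their own. Of 93444 cells given in both places, 14 differ, in 6 genes. The tables by sex were used throughout, and that table served as an alternative. Cuffdiff gave the status FAIL to 28 cells, in 10 genes, and these cells were kept as given. Gene names were matched to RefSeq GRCm38.p6 for positions, 21523 by symbol and 1676 by synonym, while 162 found no match.

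Libraries were grouped by sex, placental genotype and genotype of the dam, as the labels give them, which makes 8 groups of 2 to 4 libraries. Counts were tested with edgeR 4.0.16 under R 4.3.3: TMM normalisation, filterByExpr by group, a quasi-likelihood fit and an F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Females were fitted together (11 libraries, 15075 genes, 7 residual degrees of freedom), and so were males (8 libraries, 14965 genes, 4 residual degrees of freedom). Comparisons between the sexes, and the tests of whether a mutant effect differed between the sexes, used all 19 libraries (15308 genes, 11 residual degrees of freedom). Expression is given as counts per M fragments (CPM; M, mega) with TMM factors, as mean ± SD. A gene is said to have risen, fallen or changed only where its adjusted p passed the threshold.

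The 29 gene lists, the genes to be named, the tests and the first set of alternatives were chosen before the data were examined. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and a prior count of 2, two-sided, and adjusted over the lists of a comparison. An estimated correlation between members served as the alternative. A list needed 3 measured genes, which left the mitochondrially encoded genes untested, and the Y-linked genes were not tested within females. Members past the threshold were counted over all genes tested and again adjusted over the list alone.

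Genes were named by a fixed rule. Mcm2 and Mcm4 came first, then Xist and the Y-linked genes in every group. The comparison of C3Gt placentas of heterozygous dams with wild-type placentas took up to 8 genes in each direction, and the others up to 5. These were the genes of largest log2 fold change among those past the threshold, with a mean log2 CPM of at least 1, with groups that did not overlap and with a name other than a clone or locus number. From each list that passed its test, or had at least 3 members past the threshold, up to 4 members with the smallest adjusted p were taken. Cdkn1a, Il10rb, Ptgs2, Tnf, Il1b and Il6 were named in advance, and Il6 did not pass the filter. Members of near-identical families (Prl2c and Prl3d genes, cathepsins, Psg genes, globins and granzymes) share reads, so their levels are uncertain. Epor, in the females, and 0610010B08Rik were named after their values were seen.

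The pairing of libraries across groups is not given by the labels. Shared replicate numbers were checked for pairing by the correlation of residuals and did not pair the libraries. The closest replicates of a group still differed by a chi-square of 10.3 per degree of freedom, so none is a copy of another of its group.

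The fit was tested on counts simulated at the study's group sizes and depths. Of 67 genes changed by 2-fold, C3Gt of heterozygous dams against wild-type recovered 48 in females and 22 in males. Of 66 changed by 4-fold it recovered 63 and 51, and of 67 by 1.5-fold 21 and 2. False calls were 7 of 14916 genes and 10 of 14794. The comparison of the sexes recovered 40 of the 67 genes changed by 2-fold, and the test of a differing effect 21. Real females had far more calls (5186), so these figures may not carry over. In each comparison a raised list passed camera and an unchanged list did not, too few lists to measure false calls.

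The count of called genes in each comparison was also computed with RLE size factors in place of TMM, without the count filter, with DESeq2 1.42.0, with the replicate number as a block, with a decidual marker score as covariate, with only the groups compared, and without each library of those groups in turn. All 19 libraries in a single fit served for the comparisons within a sex, and autosomal genes only for those between the sexes. Lists were not tested with DESeq2 or with autosomal genes only, and the correlation of fold changes was computed again with RLE, without the count filter, with autosomal genes only and without each library. After the data were seen, log2 Rn45s as a covariate in the comparisons with wild-type, the table of the C3/C3 placentas, and the sex comparisons without the genes that differ between tables were added.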

Results

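Gene expression was measured in 19 mouse placentas at E13.5, from embryos of known sex. Wild-type placentas came from wild-type dams (3 females, 2 males). The mutants carried Chaos3 (C3), an allele of Mcm4, which codes for a subunit of the MCM helicase that unwinds DNA at replication origins. C3 placentas were Mcm4 C3/C3 from C3/C3 dams (2 females, 2 males). C3Gt placentas also carried, by label, 1 Gt allele of Mcm2, another subunit of the helicase. They came either from C3/C3 dams (2 females, 2 males) or from heterozygous dams, which were Mcm4 C3/+ Mcm2 Gt/+ (4 females, 2 males). The series asks whether female and male transcriptomes differ when replication is impaired and when the dam differs. Depth, in M fragments, was 17.6 to 19.2 in wild-type females, 16.05 to 18.7 in wild-type males, 16.9 to 23.5 in C3 females and 18.3 to 19.2 in C3 males. Among C3Gt placentas, females and males of C3/C3 dams had 14.8 to 16.2 and 16.9 to 17.9, and those of heterozygous dams 15.95 to 18.3 and 20.3 to 22.99. No label says whether placentas of a group came from separate litters, so every p measures the spread between these samples. Wild-type and mutant placentas differ in the dam as well as in the placenta, and these cannot be separated.

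Mcm2 did not follow its label in every library. Relative to the mean of Mcm3 to Mcm7, the other helicase subunits, Mcm2 stood at 0.847 ± 0.053 (SD, n = 9) in the libraries labelled without Gt, with a lowest value of 0.733 in wild-type male 1. Among the 10 libraries labelled Gt/+, 4 lay below all of these: C3Gt male 2 of C3/C3 dams at 0.524, and of heterozygous dams female 4 at 0.404, male 1 at 0.510 and male 2 at 0.379. The other 6 libraries labelled Gt/+ lay between 0.812 and 0.924. In CPM, Mcm2 was 40.7, 42.5 and 40.5 in the wild-type females and 35.2 and 42.4 in the wild-type males. C3 females had 48.4 and 48.0, and C3 males 57.2 and 57.8. C3Gt females of C3/C3 dams had 52.3 and 28.8 and males 52.5 and 29.6. In C3Gt placentas of heterozygous dams Mcm2 was 48.5, 38.1, 47.6 and 19.97 in females and 30.9 and 9.44 in males. Mcm2 lies on chromosome 6 at 88883474 to 88898780, and Mcm4 on chromosome 16 at 15623897 to 15637400 (RefSeq GRCm38.p6, as for all positions here). Neither gene passed the test in any comparison.

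**Figure D1:**
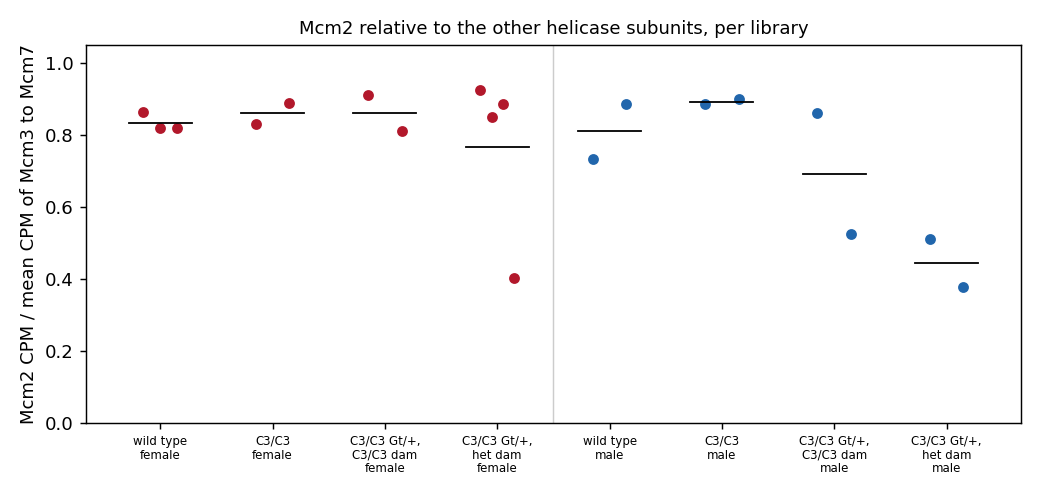
Mcm2 relative to the mean of Mcm3 to Mcm7 (ratio of CPM) in each library, by group; points are libraries and bars are group means. Of the 10 libraries labelled Gt/+, 4 lie between 0.379 and 0.524 and 6 between 0.812 and 0.924.

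The sex of each library matched its label. The sum of the 4 Y-linked genes was 86.7 to 128 CPM in males and 0 to 6.51 CPM in females, and Xist, the RNA that silences an X chromosome (X, 103460373 to 103483233), was 305 to 2041 CPM in females and 31.2 to 239 CPM in males. Another measure set groups apart. Rn45s, the precursor of ribosomal RNA, took 1.38 to 1.99% of fragments in 5 wild-type and 0.195 to 0.869% in 14 mutant libraries. Lars2, the mitochondrial leucyl-tRNA synthetase, followed, with 3576 to 4190 CPM in wild-type and 193 to 1805 CPM in mutants. Every comparison with wild-type thus also compares low with high Rn45s, as does C3Gt of C3/C3 dams (0.195 to 0.2425%) against other mutants (from 0.343%). The libraries also differed in tissue content within groups: the yolk sac endoderm markers ran from -4.13 (C3Gt female 3 of heterozygous dams) to 2.39 (C3Gt male 2 of C3/C3 dams) on the log2 scale around the mean of the 19 libraries.

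**Figure D2:**
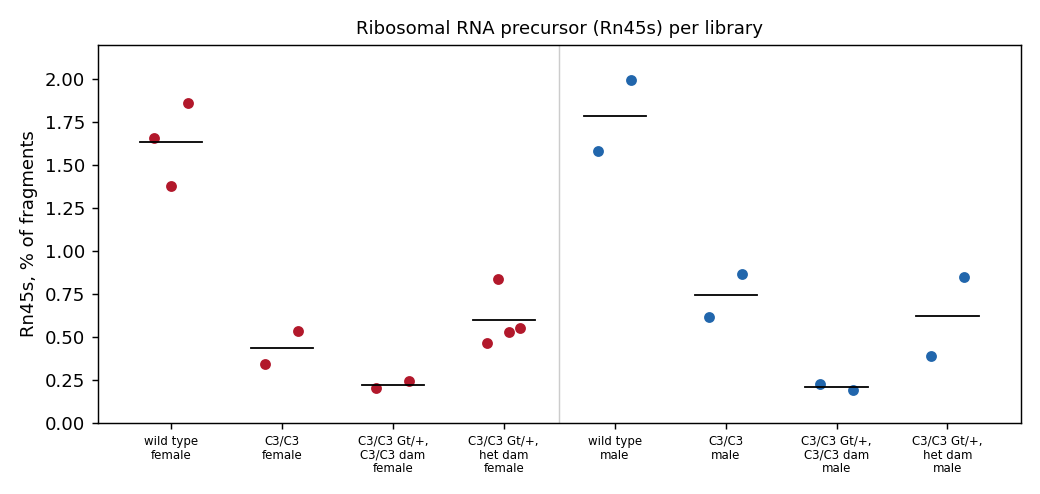
Rn45s as a percentage of all fragments in each library, by group; points are libraries.

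The first comparison asked how female C3Gt placentas of heterozygous dams (n = 4) differ from female wild-type placentas (n = 3). Genes of the spongiotrophoblast, the hormone-secreting layer between labyrinth and decidua, mostly fell. Tpbpa, the marker of this layer (chromosome 13, 60938492 to 60941936), was 8238 ± 3245 CPM in the mutants and 24138 ± 2569 CPM in wild-type placentas, a log2 fold change of -1.55 (adjusted p = 0.00459). Its neighbour Tpbpb (-1.68) and the prolactin-family hormones Prl8a9 (-1.50) and Prl8a6 (-1.03) fell as well. Of the 16 spongiotrophoblast markers, 0 rose, 13 fell and 3 did not pass. Placental lactogen Prl3b1, of giant cells, fell (-1.15), and Plac8, of glycogen trophoblast, had 430 ± 14.3 CPM against 898 ± 87.5 CPM (-1.06). Of the trophoblast giant cell markers 7 of 12 fell and of the glycogen trophoblast markers 4 of 7, while 0 rose in either. For every gene called in this comparison and named here, the 4 mutant libraries all lay on one side of the 3 wild-type libraries.

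Several red cell genes were higher in the same placentas. Slc4a1, the anion exchanger of the red cell membrane (chromosome 11, 102348820 to 102365281), had 28.7 ± 10.8 CPM against 5.55 ± 1.40 CPM (2.38, adjusted p = 0.00138). The membrane protein Epb4.2 (2.69) and the embryonic globins Hbb-bh1 (2.17) and Hba-x (1.75) rose too, though globin genes share reads. In the erythroid genes 10 of 16 members rose and 1 fell, Epor, the erythropoietin receptor (7.07 ± 3.45 CPM against 17.8 ± 0.430 CPM, -1.33, adjusted p = 0.0144, and 0.266 with the decidual score as covariate). Kdr, the main receptor of VEGF on endothelium (chromosome 5, 75932827 to 75979072), rose from 50.6 ± 3.73 to 144 ± 52.1 CPM (1.51, adjusted p = 0.00209). Some targets of low oxygen signalling rose: Adm had 244 ± 104 CPM against 78.8 ± 10.4 CPM (1.63), Egln3 rose by 1.40 and the glycolytic enzyme Hk2 by 1.31 on the log2 scale. Hypoxia and glycolysis counted 9 risen and 2 fallen members of 24 (adjusted p = 0.207 for the list), and the endothelial markers 4 risen and 0 fallen of 15 (adjusted p = 0.173).

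Some steroid and decidual genes rose in the same placentas. Esr1, the oestrogen receptor (chromosome 10, 4611989 to 5005633), had 35.0 ± 15.6 CPM against 7.80 ± 2.03 CPM (2.16, adjusted p = 0.00184), and Pgr, the progesterone receptor (chromosome 9, 8898900 to 8968611), 97.3 ± 49.1 CPM against 26.0 ± 6.83 CPM (1.90, adjusted p = 0.00362). The steroid synthesis and receptors list had 5 risen and 2 fallen members of 10 (adjusted p = 0.204). Among the decidual stroma markers, 6 of 13 rose, Hoxa10 (1.67) and Hoxa11 (1.51) with them, and Prl3c1 fell (7.18 ± 3.65 CPM against 26.9 ± 2.50 CPM, -1.91); the list did not pass (adjusted p = 0.116, median log2 1.15).

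Stress and damage genes went both ways. Sdf2l1, a chaperone of the endoplasmic reticulum (chromosome 16, 17130138 to 17132383), fell from 148 ± 14.6 to 81.5 ± 3.89 CPM (-0.86, adjusted p = 9.98e-04). Creld2, a member of the same list, fell by 0.72. The unfolded protein and integrated stress response list had 2 risen and 9 fallen members of 24. Atm, the kinase that signals DNA breaks, rose from 6.42 ± 0.163 to 10.96 ± 0.543 CPM (0.77), and the DNA damage signalling and repair list had 5 risen and 2 fallen members of 21 (adjusted p = 0.228). Among the p53 targets 7 of 28 rose and 4 fell (adjusted p = 0.267). Cdkn1a, the p53-induced inhibitor of the cell cycle (chromosome 17, 29090979 to 29100722), was 78.5 ± 31.7 CPM against 43.2 ± 6.24 CPM (0.86, adjusted p = 0.0296). Its call was lost without wild-type female 1 (adjusted p = 0.0582), 2 (0.0789) or 3 (0.111), without mutant female 2 (0.0647), and with the decidual score as covariate (0.882).

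Inflammatory genes gave a mixed picture. In the NF-kB and inflammatory cytokines list 7 of 31 members rose and 1 fell, the neutrophil attractant Cxcl1 (2.81 ± 0.982 CPM against 8.17 ± 0.972 CPM, -1.53, adjusted p = 0.00343). Tnf had 1.17 ± 0.484 CPM against 0.596 ± 0.0796 CPM (0.97, adjusted p = 0.0591), called without mutant female 1 (0.0292) or 3 (0.0447), and Il1b had 3.22 ± 1.16 CPM against 3.11 ± 0.236 CPM (0.05, adjusted p = 0.923). Il10rb, a subunit of the IL-10 receptor, had 44.4 ± 4.13 CPM against 43.0 ± 3.16 CPM (0.05, adjusted p = 0.728). Ptgs2, which starts prostaglandin synthesis, had 18.6 ± 3.40 CPM against 15.7 ± 0.573 CPM (0.25, adjusted p = 0.203), and was called without mutant female 3 (adjusted p = 0.0129). Ptges, the prostaglandin E synthase, rose from 30.1 ± 1.06 to 67.2 ± 14.8 CPM (1.16), with 4 risen and 3 fallen of 18 in the IL-10 and prostaglandin pathway (adjusted p = 0.545). Of 37 genes of the interferon response 3 rose and 2 fell (adjusted p = 0.467). Oas1a, an antiviral synthetase, fell from 45.7 ± 1.65 to 33.9 ± 2.88 CPM (-0.43). Macrophage markers had 4 risen of 17 (adjusted p = 0.267) and 0 adjusted over the list alone, neutrophil markers 1 of 9 (adjusted p = 0.401), and uterine NK and T cell markers 0 of 13 (adjusted p = 0.791).

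Some of the largest changes lay outside the lists. Acsl6, a fatty acid CoA ligase (chromosome 11, 54303805 to 54364756), went from 0.233 ± 0.107 to 24.6 ± 13.7 CPM (6.69, adjusted p = 0.00566, from 3 to 6 fragments per wild-type library). Coch, an extracellular matrix protein (chromosome 12, 51593283 to 51606619), rose from 31.5 ± 14.9 to 224 ± 128 CPM (2.83). Large falls were seen in Erdr1 (X, 170010526 to 170018797; 43.0 ± 10.9 CPM against 174 ± 15.4 CPM, -2.02), in Ceacam12 (-1.86) and in Lars2 (chromosome 9, 123366927 to 123462675; -1.84). Xist was 701 ± 151 CPM against 310 ± 10.5 CPM (1.17, adjusted p = 0.0102). Of 31 imprinted genes 8 rose and 2 fell (adjusted p = 0.204). The other lists did not pass: 0 of 6 in the MCM helicase, 4 risen and 13 fallen of 55 in DNA replication (adjusted p = 0.116), and 2 risen and 1 fallen of 30 in mitosis (adjusted p = 0.525). Complement and coagulation had 3 risen of 19 (adjusted p = 0.718), labyrinth trophoblast markers 3 risen and 1 fallen of 16 (0.773), yolk sac endoderm markers 0 of 12 (0.221), cholesterol synthesis 1 risen and 2 fallen of 24 (0.84), immediate early genes 6 risen and 2 fallen of 15 (0.207), and Xist and X genes that escape inactivation 2 risen and 1 fallen of 10 (0.773). Among the lists that did not pass, the counts of risen and fallen members adjusted over the list alone differed from those over all genes in 11: DNA replication (3 and 13), mitosis (0 and 0), p53 targets (8 and 4), the IL-10 and prostaglandin pathway (6 and 3), complement and coagulation (1 and 0), macrophage markers (0 and 0), decidual stroma markers (8 and 1), endothelial markers (1 and 0), cholesterol synthesis (0 and 0), hypoxia and glycolysis (10 and 2) and immediate early genes (7 and 3).

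In all, edgeR called 5186 genes here, 2814 higher and 2372 lower, of which 1078 changed at least 2-fold. It called 2985 with the decidual score as covariate, of which 2357 were among the 5186. Camera called 6 lists: spongiotrophoblast markers (adjusted p = 1.27e-04, median log2 -1.28), trophoblast giant cell markers (0.00852, -0.64), glycogen trophoblast markers (0.0293, -0.65), erythroid genes (0.0293, 1.34), NF-kB and inflammatory cytokines (0.0432, 0.46) and the unfolded protein and integrated stress response (0.0436, -0.15). Each of the 6 had adjusted p = 0.876 with an estimated correlation. Adjusted over the list alone, the fallen members were 13, 9 and 4 in the 3 trophoblast lists, and the risen members 10 in the erythroid genes and 6 in the NF-kB and inflammatory cytokines. With log2 Rn45s as covariate, which the groups nearly fix, 0 genes were called. The trophoblast giant cell markers (adjusted p = 0.104) and the unfolded protein and integrated stress response (0.121) then lost their calls. The count was 3186 without wild-type female 1 and 3138 without wild-type female 3. NF-kB and inflammatory cytokines lost their call without wild-type female 3 (0.064), mutant female 2 (0.0964) or 4 (0.0586), glycogen trophoblast markers without mutant female 2 (0.0513) and erythroid genes without wild-type female 2 (0.0566) or mutant female 3 (0.107). The same held for the unfolded protein and integrated stress response without wild-type female 1 (0.0941) or 2 (0.0566) or mutant female 1 (0.0699), 2 (0.0585) or 3 (0.0849). A decidual score as covariate ended the calls of glycogen trophoblast markers (0.225), trophoblast giant cell markers (0.166) and NF-kB and inflammatory cytokines (0.432).

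**Figure D3:**
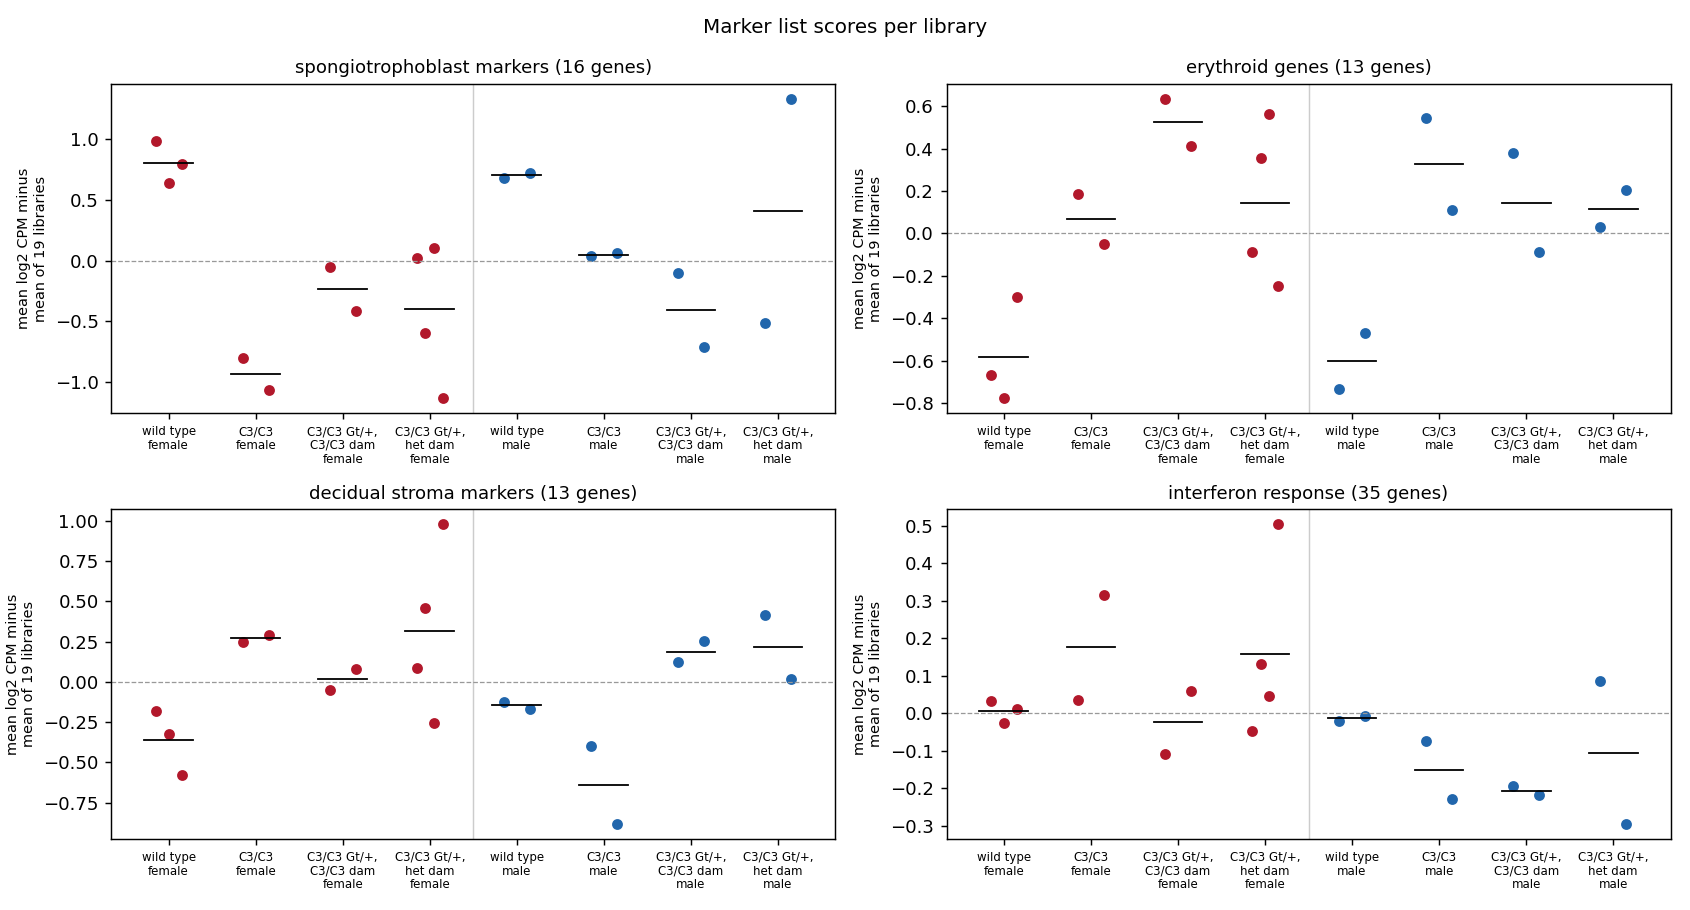
Scores of 4 gene lists in each library (mean log2 CPM of the members minus the mean of the 19 libraries), by group; points are libraries and lines are group means. The panels show the spongiotrophoblast markers, the erythroid genes, the decidual stroma markers and the interferon response.

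The same question was asked of C3Gt females of C3/C3 dams (n = 2) against the 3 wild-type females. Slc4a1 rose from 5.55 ± 1.40 to 60.6 ± 1.59 CPM (3.45, adjusted p = 2.4e-04), and Sptb, the red cell spectrin, rose by 2.48. Of 16 erythroid genes 9 rose and 1 fell, Epor (6.71 ± 0.727 CPM, -1.41, adjusted p = 0.0286, lost without any 1 of the 5 libraries, at 0.0631 to 0.151). Spongiotrophoblast markers had 9 fallen and 0 risen of 16, with Tpbpb at -1.69, and trophoblast giant cell markers 4 fallen of 12, with Prl3b1 at -1.17. Atm had 15.7 ± 0.835 CPM against 6.42 ± 0.163 CPM (1.29, adjusted p = 2.36e-04), and Brca2 (0.95) and Atr (0.65), which act in repair and in the response to stalled forks, rose as well, while Rad9a fell (-0.65). Gins4 (-0.61) and Rfc2 (-0.48) were among 11 fallen members of DNA replication, beside 5 that rose. Rtl1, a placental imprinted gene (chromosome 12, 109564900 to 109604418), rose from 4.95 ± 0.425 to 17.6 ± 0.805 CPM (1.83, adjusted p = 3.2e-04), and Zim1 (1.34), Plagl1 (1.03) and Igf2r (1.02) rose with it, making 8 risen and 2 fallen of 31 imprinted genes.

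Immune genes in these placentas moved in both directions. Itgam, an integrin of macrophages and neutrophils, rose from 2.24 ± 0.535 to 7.58 ± 2.43 CPM (1.76, adjusted p = 0.00171), 1 of 6 risen macrophage markers of 17 (adjusted p = 0.0727 for the list). Oas1a (26.0 ± 2.63 CPM against 45.7 ± 1.65 CPM, -0.81), Bst2 (-0.61) and Ifi44l (-2.34) fell. The interferon response had 3 risen and 5 fallen of 37 (1 and 5 adjusted over the list alone, adjusted p = 0.689 for the list). NF-kB and inflammatory cytokines had 7 risen and 0 fallen of 31. Sdf2l1 had 67.5 ± 6.46 CPM against 148 ± 14.6 CPM (-1.13), and Creld2 (-0.86), Asns (-0.64) and Xbp1 (-0.52) fell too, among 10 fallen and 0 risen of 24 in the unfolded protein and integrated stress response. Esr1 (1.76) rose, and Xist was 1431 ± 886 CPM against 310 ± 10.5 CPM (2.205, adjusted p = 9.16e-04). Each gene named as changed in this comparison was higher, or lower, in both mutants than in all 3 wild-type placentas.

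There edgeR called 5334 genes, 2707 higher and 2627 lower. The list tests passed for erythroid genes (adjusted p = 0.00523, median log2 1.73), spongiotrophoblast markers (0.00523, -1.29), the unfolded protein and integrated stress response (0.00523, -0.28), trophoblast giant cell markers (0.0464, -0.51), DNA replication (0.0472, -0.15), NF-kB and inflammatory cytokines (0.0472, 0.44) and imprinted genes (0.0496, 0.35). None held with an estimated correlation (adjusted p = 0.948 for DNA replication and 0.932 for the other 6). Adjusted over the list alone, 10 erythroid genes rose, 12 spongiotrophoblast markers fell, 11 members of the unfolded protein and integrated stress response fell and 8 imprinted genes rose. Lars2 (233 ± 54.3 CPM against 4001 ± 299 CPM, -4.10) and Rn45s (-3.02) were among the largest changes, and with log2 Rn45s as covariate 0 genes were called and trophoblast giant cell markers (adjusted p = 0.45), the unfolded protein and integrated stress response (0.086) and imprinted genes (0.667) lost their calls. With the decidual score as covariate DNA replication (0.342), NF-kB and inflammatory cytokines (0.219) and trophoblast giant cell markers (0.194) lost theirs. Without C3Gt female 2 of C3/C3 dams the count was 3511, and the calls of DNA replication (adjusted p = 0.799) and NF-kB and inflammatory cytokines (0.0521) were lost. Other single libraries ended calls as well: DNA replication without wild-type female 2 (0.0919) or 3 (0.0837), NF-kB and inflammatory cytokines without wild-type female 3 (0.0882), imprinted genes without wild-type female 1 (0.0703) or 3 (0.0837) or mutant female 1 (0.185), and trophoblast giant cell markers without wild-type female 1 (0.0530) or mutant female 1 (0.0896).

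C3 females (n = 2) were compared with the same wild-type females to ask what the Mcm4 mutation goes with when Gt is absent. Spongiotrophoblast genes were lowest here: Tpbpa had 4845 ± 360 CPM against 24138 ± 2569 CPM (-2.32, adjusted p = 0.00287), Tpbpb 902 ± 119 CPM against 5959 ± 817 CPM (-2.72), and 14 of 16 markers fell with 0 risen. Of the endothelial markers 9 of 15 rose and 0 fell (adjusted p = 0.00101 for the list, but adjusted p = 0.799 with an estimated correlation). Kdr had 169 ± 14.3 CPM against 50.6 ± 3.73 CPM (1.74, adjusted p = 0.00194), the receptor of angiopoietins Tek 38.9 ± 5.41 CPM against 14.4 ± 2.22 CPM (1.43), and Tie1 (1.30) and Pecam1 (1.04) rose as well. Sdf2l1 fell from 148 ± 14.6 to 59.7 ± 4.37 CPM (-1.31, adjusted p = 4.01e-04), with Creld2 (-1.11), Herpud1 (-0.87) and Xbp1 (-0.50), among 10 fallen and 0 risen of 24. Rtl1 (1.53), Plagl1 (1.17), Grb10 (0.94) and Igf2r (0.85) were among 9 risen imprinted genes of 31, with 1 fallen. Of 16 labyrinth trophoblast markers 6 rose and 0 fell (adjusted p = 0.174 for the list).

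Other changes in C3 females included Ptger3, a receptor of prostaglandin E, at 26.6 ± 2.36 CPM against 67.3 ± 3.72 CPM (-1.33) and Atm (0.92). The interferon response had 3 risen and 2 fallen of 37 (1 and 0 adjusted over the list alone, adjusted p = 0.342 for the list), the complement and coagulation list 6 risen and 0 fallen of 19 by both counts (adjusted p = 0.4), and the decidual stroma markers 6 risen and 1 fallen of 13 (7 and 1 over the list alone, adjusted p = 0.107). Erdr1 had 12.5 ± 2.11 CPM against 174 ± 15.4 CPM (-3.79) and Lars2 395 ± 56.4 CPM (-3.34). In this comparison 4946 genes were called, 2670 higher and 2276 lower. Camera called spongiotrophoblast markers (adjusted p = 9.69e-06, median log2 -1.94), endothelial markers (0.00101, 0.92), the unfolded protein and integrated stress response (0.00389, -0.36), trophoblast giant cell markers (0.0054, -0.66, 5 fallen of 12), imprinted genes (0.00842, 0.45) and glycogen trophoblast markers (0.0154, -0.50, 4 fallen of 7). For each, adjusted p = 0.799 with an estimated correlation. Adjusted over the list alone, 14 spongiotrophoblast markers fell, 11 endothelial markers rose, 12 members of the unfolded protein and integrated stress response fell, and 9 imprinted genes rose. With log2 Rn45s as covariate 0 genes were called, and endothelial markers (adjusted p = 0.0959), imprinted genes (0.184) and trophoblast giant cell markers (0.0956) lost their calls. With the decidual score as covariate glycogen trophoblast markers (0.192) and trophoblast giant cell markers (0.0861) lost theirs. The count was 7907 with only the groups compared, and fell to 3122 without wild-type female 1, 3188 without wild-type female 3, 2234 without C3 female 1 and 1477 without C3 female 2.

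Comparing the 2 kinds of dam, C3Gt females of heterozygous dams (n = 4) and of C3/C3 dams (n = 2) differed in no gene past the threshold. Here edgeR called 0 genes with 2275 at an unadjusted p under 0.05, against 754 expected by chance, and DESeq2 called 381. With a replicate block edgeR called 26, and 8 with the decidual score as covariate. Slc4a1 had 28.7 ± 10.8 CPM with heterozygous dams and 60.6 ± 1.59 CPM with C3/C3 dams (-1.07, adjusted p = 0.163), and Ankrd37, induced by low oxygen, 17.2 ± 5.97 CPM and 7.72 ± 2.79 CPM (1.16, adjusted p = 0.18). By camera, hypoxia and glycolysis (adjusted p = 0.00998, median log2 0.25), the unfolded protein and integrated stress response (0.00998, 0.17) and the interferon response (0.0281, 0.15) were higher with heterozygous dams, and erythroid genes lower (0.00998, -0.29). Of their members 0 passed over all genes, 6 of hypoxia and glycolysis passed adjusted over the list alone, and each list had adjusted p = 0.959 with an estimated correlation. Interferon response lost its call without C3Gt female 1 of C3/C3 dams (0.298) or female 4 of heterozygous dams (0.229), the library labelled Gt/+ with the low Mcm2 ratio; erythroid genes lost theirs without C3Gt female 1 of C3/C3 dams (0.221) or females 1 (0.0688) or 4 (0.155) of heterozygous dams, and the unfolded protein and integrated stress response without C3Gt female 2 of C3/C3 dams (0.335). Without C3Gt female 3 of heterozygous dams 186 genes were called.

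The label Gt/+ was tested by C3Gt against C3 females of C3/C3 dams (n = 2 each). Neither C3Gt female had low Mcm2 (ratios 0.911 and 0.812), so its loss was untested. Again edgeR called 0 genes (1375 at an unadjusted p under 0.05), and DESeq2 21. A replicate block gave 17 and only the groups compared 5. Tpbpb had 1841 ± 10.1 CPM in C3Gt and 902 ± 119 CPM in C3 placentas (1.03, adjusted p = 0.521) and Mcm5 41.5 ± 15.9 CPM and 57.3 ± 2.18 CPM (-0.46, adjusted p = 0.555). Spongiotrophoblast markers (adjusted p = 2.96e-04, median log2 0.82), erythroid genes (0.00184, 0.53) and macrophage markers (0.0271, 0.42) were higher by camera. Endothelial markers (2.96e-04, -0.39), mitosis (0.00179, -0.20), DNA replication (0.00179, -0.14), the interferon response (0.00179, -0.20), labyrinth trophoblast markers (0.013, -0.20) and the MCM helicase (0.0271, -0.26) were lower. All had adjusted p = 0.741 with an estimated correlation, and 0 members passed over all genes (1 of the interferon response fell over the list alone). Without C3Gt female 2 of C3/C3 dams the medians of the MCM helicase (0.06) and mitosis (0.07) turned, as did the test of DNA replication (median -0.03), and macrophage markers (adjusted p = 0.277), endothelial markers (0.198) and labyrinth trophoblast markers (0.619) lost their calls. Without C3Gt female 1 of C3/C3 dams spongiotrophoblast markers (0.108), the interferon response (0.179) and erythroid genes (0.213) lost theirs, and so did the MCM helicase (0.127), macrophage markers (0.113) and labyrinth trophoblast markers (0.0978) without C3 female 1 and the interferon response (0.304) and erythroid genes (0.0578) without C3 female 2.

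Males were compared in the same way with 2 wild-type males. In C3Gt males of heterozygous dams (n = 2), Acsl6 had 25.7 ± 22.8 CPM against 0.118 ± 0.0743 CPM (1 and 3 fragments in the wild-type males, adjusted p = 0.0404), Mamdc2, a proteoglycan of the matrix (chromosome 19, 23302609 to 23448497), 15.5 ± 1.84 CPM against 1.98 ± 0.0681 CPM (2.97), and Inhba, a subunit of activin (chromosome 13, 16004256 to 16031609), 145 ± 4.37 CPM against 34.2 ± 1.09 CPM (2.08, adjusted p = 0.0404). Rtl1 (1.77) and Peg3 (585 ± 39.3 CPM against 265 ± 9.97 CPM, 1.14) were among 4 risen imprinted genes of 31 with 1 fallen (adjusted p = 0.1253 for the list). Slc4a1 (2.06) and Epb4.2 (2.96) were among 3 risen erythroid genes with 0 fallen (adjusted p = 0.1253). Cdkn1a had 64.3 ± 18.99 CPM against 50.4 ± 1.41 CPM (0.35, adjusted p = 0.41), Tnf 0.64 (adjusted p = 0.314), Il1b 1.02 (0.403), Ptgs2 0.45 (0.177) and Il10rb -0.14 (0.519) on the log2 scale. For each gene named as changed, both mutants lay on one side of both wild-type males.

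For these males edgeR called 1221 genes, 788 higher and 433 lower, and DESeq2 2423. The only list that passed was DNA replication, with 0 risen and 2 fallen of 55 members (Rpa3 -0.78, Rfc2 -0.63; adjusted p = 2.71e-04, median log2 -0.26; adjusted p = 0.862 with an estimated correlation; 2 fallen adjusted over the list alone). It lost its call without male 2 (median 0.04, adjusted p = 0.868), a library that lay apart, with scores of -1.21 for the MCM helicase and -1.33 for mitosis. The count was 0 without wild-type male 1 or without wild-type male 2, 233 without mutant male 1, 0 with the decidual score as covariate and 1 with log2 Rn45s as covariate. It was 0 with a replicate block, 714 with only the groups compared and 3106 with all 19 libraries in a single fit.

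C3Gt males of C3/C3 dams (n = 2) had 2347 called genes, 1196 higher and 1151 lower. Some cholesterol genes rose: Ldlr, the LDL receptor, had 218 ± 2.96 CPM against 124 ± 5.96 CPM (0.81, adjusted p = 0.0286), and Stard4 (1.23), Dhcr24 (0.70) and Hmgcr (0.64) rose, making 5 risen and 0 fallen of 24 (adjusted p = 0.0301 for cholesterol synthesis, but adjusted p = 0.871 with an estimated correlation, and a median turned to -0.40 with log2 Rn45s as covariate). Among the imprinted genes Rtl1 (1.54), Peg3 (1.12), Plagl1 (1.12) and Zim1 (0.95) were among 7 risen with 1 fallen. In the interferon response 0 rose and 6 of 37 fell (adjusted p = 0.0685 for the list), with Oas1a at 25.1 ± 2.94 CPM against 45.6 ± 1.01 CPM (-0.86), Bst2 (-0.73) and Isg15 (-0.71). Slc4a1 (37.1 ± 17.8 CPM against 5.19 ± 2.06 CPM, 2.83), Kdr (0.81) and Tek (0.93) rose, and Sdf2l1 (-0.92) fell. The Y-linked helicase Ddx3y rose from 48.8 ± 3.57 to 73.8 ± 1.33 CPM (0.60, adjusted p = 0.0286). Both mutants lay on one side of both wild-type males for each of these genes. Imprinted genes passed camera with the same values (medians on the log2 scale 0.48 for cholesterol synthesis and 0.47 for imprinted genes); adjusted over the list alone 6 and 13 members rose. Counts were 0 without wild-type male 1, wild-type male 2 or mutant male 2, 1458 without mutant male 1, and 0 with either the decidual score or log2 Rn45s as covariate. They were 559 with a replicate block, 3731 with only the groups compared and 3990 with all 19 libraries in a single fit. Cholesterol synthesis lost its call without wild-type male 1 (0.115) or mutant male 2 (0.112), and imprinted genes without wild-type male 2 (0.0663).

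In C3 males (n = 2) edgeR called 0 genes, with 3932 at an unadjusted p under 0.05 against 748 expected by chance, and DESeq2 called 1600. Other fits by edgeR called 2241 with only the groups compared, 2148 with all 19 libraries in a single fit and 308 without the count filter. Levels lay apart from wild-type males all the same: Sdf2l1 had 73.1 ± 5.32 CPM against 147 ± 7.83 CPM (-1.01), Slc4a1 33.2 ± 6.45 CPM against 5.19 ± 2.06 CPM (2.67) and Rtl1 12.6 ± 2.98 CPM against 3.37 ± 1.07 CPM (1.91), each with adjusted p = 0.0632. Camera put imprinted genes (adjusted p = 2.11e-04, median log2 0.49), endothelial markers (0.00222, 0.56), erythroid genes (0.00532, 1.03), mitosis (0.00676, 0.59) and labyrinth trophoblast markers (0.0281, 0.32) higher. Uterine NK and T cell markers (0.00144, -1.72), the unfolded protein and integrated stress response (0.00532, -0.24) and hypoxia and glycolysis (0.0121, -0.18) were lower. With an estimated correlation the lowest adjusted p = 0.566, and adjusted over the list alone 14 imprinted genes, 5 endothelial markers, 3 erythroid genes and 6 labyrinth trophoblast markers were higher and 7 uterine NK and T cell markers and 10 members of the unfolded protein and integrated stress response lower. Labyrinth trophoblast markers lost their call without wild-type male 2 (0.0596) or C3 male 2 (0.0691), and uterine NK and T cell markers with the decidual score as covariate (0.0927). With log2 Rn45s as covariate the medians of mitosis (-0.89) and of hypoxia and glycolysis (0.0014) turned.

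Among mutant males the dam and the label Gt/+ again gave 0 called genes by edgeR. Between C3Gt males of heterozygous and of C3/C3 dams, 780 genes had an unadjusted p under 0.05 and DESeq2 called 42. Camera put cholesterol synthesis (adjusted p = 3.18e-12, median log2 -0.56; adjusted p = 0.733 with an estimated correlation), DNA replication (4.3e-13, -0.38) and mitosis (7.56e-13, -0.66) lower with heterozygous dams; Ldlr had 146 ± 8.69 CPM against 218 ± 2.96 CPM (-0.58, adjusted p = 0.663). The MCM helicase (0.00245, -0.49) and DNA damage signalling and repair (1.44e-04, -0.20) were lower, and spongiotrophoblast markers (0.0199, 1.08), hypoxia and glycolysis (0.00253, 0.15) and immediate early genes (0.00687, 0.16) higher. With an estimated correlation adjusted p = 0.767 for DNA replication, mitosis, the MCM helicase and DNA damage signalling and repair, 0.733 for hypoxia and glycolysis and immediate early genes, and 0.872 for spongiotrophoblast markers. Several of these calls rested on male 2 of heterozygous dams: without it DNA replication (median 0.02, adjusted p = 0.496), mitosis (-0.03, 0.109), the MCM helicase (0.04, 0.874), DNA damage signalling and repair (-0.02, 0.684) and hypoxia and glycolysis (0.07, 0.437) were not called, and spongiotrophoblast markers had the median -0.20. Spongiotrophoblast markers also lost their call without C3Gt male 2 of C3/C3 dams (0.56), the MCM helicase without C3Gt male 1 of C3/C3 dams (0.135), and immediate early genes without male 1 of heterozygous dams (0.0573). Without male 1 of heterozygous dams 350 genes were called.

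Between C3Gt and C3 males of C3/C3 dams, 1449 genes had an unadjusted p under 0.05 and DESeq2 called 331. Pgr had 77.6 ± 7.74 CPM in C3Gt and 24.3 ± 7.75 CPM in C3 placentas (1.68, adjusted p = 0.197). Decidual stroma markers (adjusted p = 5.36e-04, median log2 1.07, 6 higher adjusted over the list alone), uterine NK and T cell markers (0.00212, 1.16) and cholesterol synthesis (0.00276, 0.26) were higher in C3Gt placentas, and labyrinth trophoblast markers (0.00444, -0.34) and yolk sac endoderm markers (0.0286, -0.36) lower. With an estimated correlation adjusted p = 0.708 for these lists and 0.857 for yolk sac endoderm markers. With the decidual score as covariate, uterine NK and T cell markers (-0.14) and cholesterol synthesis (-0.31) turned direction, as the decidual stroma markers that make up the score did (-0.14). Cholesterol synthesis lost its call without C3Gt male 2 (0.532) or C3 male 2 (0.299), labyrinth trophoblast markers without C3Gt male 2 (0.079) or C3 male 2 (0.0983), and yolk sac endoderm markers without C3 male 1 (0.166), with the median 0.61 without C3Gt male 1.

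Fold changes of females and males against their own wild-type placentas, which share no library, were compared across 14820 genes. In C3Gt placentas of C3/C3 dams Pearson's r was 0.73 and Spearman's rho 0.79, with the same sign in 83.2% of all genes. In both sexes 1037 genes rose against 217 expected by chance, 961 fell against 203, and 0 were called in opposite directions. For heterozygous dams r was 0.66 and rho 0.74, with 703 genes risen in both sexes against 149 expected, 399 fallen in both against 68.8, and 0 opposite. For C3 placentas r was 0.43 and rho 0.53. Genes are not independent replicates, so no p is given. In both sexes Rn45s was higher in the wild-type libraries. Without the count filter r was 0.41, 0.31 and 0.23 in the same order, and without male 1 of heterozygous dams it was 0.36 for their placentas, while without wild-type male 2 it was 0.27 for C3 placentas.

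The question of the series, whether the sexes differ, was tested within each group. Among wild-type placentas edgeR called 6 genes, with 193 at an unadjusted p under 0.05, and DESeq2 called 11. Females lacked the Y-linked genes Ddx3y (0.325 ± 0.463 CPM against 49.0 ± 3.56 CPM, n = 3 and 2), Eif2s3y, Uty and Kdm5d, and Xist had 311 ± 9.91 CPM against 33.9 ± 3.79 CPM (3.20, adjusted p = 0.0473), a call lost without any 1 of the 5 libraries (adjusted p of 0.131 to 0.822) and without the genes that differ between tables (0.0568). The sixth, Syne1, depends on the table. C3 males had 1 and 2 fragments in the table of males but 403 and 522 in that of the C3 placentas. Its calls thus do not show a sex difference. The Y-linked genes (adjusted p = 2.44e-36) and Xist and X genes that escape inactivation (2.52e-13, 4 higher adjusted over the list alone) also held with an estimated correlation (5.27e-04 and 0.00384), and with the Y-linked genes of the other groups they were the only list calls that did. Macrophage markers (0.0016, median log2 -0.32), uterine NK and T cell markers (0.0275), NF-kB and inflammatory cytokines (0.0275), the IL-10 and prostaglandin pathway (0.0289), complement and coagulation (0.0289) and hypoxia and glycolysis (0.0289) were lower in wild-type females by camera, with 0 members called and with adjusted p of 0.582 or higher with an estimated correlation. Without male 1 or without female 3 calls were lost for NF-kB and inflammatory cytokines (0.113 and 0.192), the IL-10 and prostaglandin pathway (0.141 and 0.0761), complement and coagulation (0.169 and 0.348) and uterine NK and T cell markers (0.186 and 0.333). Hypoxia and glycolysis lost its call without female 1 (0.13), female 3 (0.0693) or male 2 (0.337), and the IL-10 and prostaglandin pathway without female 2 (0.0811).

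C3 females and males (n = 2 each) differed in the same 4 Y-linked genes, Xist (461 ± 26.0 CPM against 38.0 ± 5.81 CPM, 3.60, adjusted p = 0.0226) and Syne1, with 1908 genes at an unadjusted p under 0.05 and 208 called by DESeq2. With only the groups compared edgeR called 913, with a replicate block 385 and in the table of the C3 placentas 911. Decidual stroma markers (adjusted p = 4.2e-05, median log2 1.053), uterine NK and T cell markers (6.86e-05, 1.71) and the interferon response (5.85e-05, 0.33) were higher in females by camera, and spongiotrophoblast markers (5.65e-05, -1.06), trophoblast giant cell markers (1.77e-04, -0.61) and yolk sac endoderm markers (0.00532, -2.68) lower. The lowest adjusted p was 0.38 with an estimated correlation, apart from the Y-linked genes; adjusted over the list alone 8 uterine NK and T cell markers and 4 decidual stroma markers were higher. With the decidual score as covariate the medians were -0.31 for decidual stroma markers, -0.03 for the interferon response, 0.11 for uterine NK and T cell markers and 0.34 for spongiotrophoblast markers. Xist lost its call without any 1 of the 4 libraries (adjusted p of 0.0742 to 0.285), Ddx3y (0.0602 and 0.0702) and Kdm5d (0.0602 and 0.067) without C3 female 1 or 2, Uty (0.067) without C3 female 2, and Syne1 in the table of the C3 placentas (0.17).

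In C3Gt placentas of C3/C3 dams the sexes again differed in the 4 Y-linked genes, Xist (1420 ± 879 CPM against 140 ± 88.0 CPM, n = 2 each, 3.34, adjusted p = 0.042) and Syne1, with 1091 genes at an unadjusted p under 0.05 and 16 called by DESeq2. With only the groups compared Syne1 alone was called; adjusted p was 0.0811 to 0.783 for the Y-linked genes and 0.939 for Xist. Macrophage markers (adjusted p = 0.00238, median log2 0.52), uterine NK and T cell markers (0.0127, 0.84), erythroid genes (0.0402, 0.49) and the interferon response (0.00729, 0.17) were higher in females by camera. Cholesterol synthesis (1.07e-07, -0.29), DNA replication (1.13e-06, -0.19), mitosis (1.63e-06, -0.41) and the unfolded protein and integrated stress response (1.63e-06, -0.25) were lower. With an estimated correlation each had adjusted p of 0.372 or higher, and 0 members passed adjusted over these lists alone. Without female 2 the calls of mitosis (0.272), DNA replication (0.0516), macrophage markers (0.0513), uterine NK and T cell markers (0.0848) and the interferon response (0.0977) were lost, and without male 2 those of the interferon response (0.0788), uterine NK and T cell markers (0.109), erythroid genes (0.502) and cholesterol synthesis (0.065). Macrophage markers lost theirs without male 1 (0.355), erythroid genes without female 1 (0.465), Xist without male 1 (0.388), female 2 (0.47) or the genes that differ between tables (0.0504), and Ddx3y (0.0824), Uty (0.0648) and Kdm5d (0.0648) without female 2.

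C3Gt females (n = 4) and males (n = 2) of heterozygous dams differed in 7 genes: the 4 Y-linked genes, Syne1, Rec8, a cohesin of meiosis (chromosome 14, 55618002 to 55625395; 20.7 ± 1.46 CPM against 11.5 ± 1.29 CPM, 0.85, adjusted p = 0.0189) and 0610010B08Rik on chromosome 2, named after its values were seen (0 in all 4 females and 1.08 ± 0.310 CPM in males, adjusted p = 0.0497, lost without any 1 of the females, at 0.0716 to 0.112, or male 2, 0.459). Like Syne1 this gene depends on the table: the C3 females had 0 and 0 of its fragments in the table of females but 20 and 22 in the table of the C3 placentas, so its 0 in females may not be real. Rec8 lost its call without female 1 (0.068), female 3 (0.0546) or male 2 (0.856). At an unadjusted p 880 genes were under 0.05 and DESeq2 called 14. With only the groups compared Syne1 alone was called; adjusted p was 0.123 to 0.234 for the Y-linked genes and 0.9998 for Rec8. Interferon genes had higher means in females but none was called: Oasl2 (chromosome 5, 114896926 to 114912245) had 69.2 ± 6.14 CPM against 45.0 ± 14.5 CPM, Oas1a 33.9 ± 3.39 CPM against 26.4 ± 1.38 CPM and Bst2 221 ± 25.4 CPM against 175 ± 8.19 CPM, each with adjusted p = 0.679. As a list the interferon response passed (adjusted p = 2.32e-08, median log2 0.32; adjusted p = 0.562 with an estimated correlation), with 5 members of 38 higher adjusted over the list alone and 0 over all genes. Its median was 0.13 without male 2, 0.21 without female 4 and 0.54 without male 1, and in wild-type placentas it was 0.03 (adjusted p = 0.704). Mitosis (9.45e-11, 0.31) and DNA replication (1.73e-10, 0.21) were higher and spongiotrophoblast markers (5.82e-07, -0.94) lower in females, with adjusted p of 0.565 with an estimated correlation. Without male 2, the library apart, the medians were -0.30 for mitosis, -0.13 for DNA replication and 0.34 for spongiotrophoblast markers (adjusted p = 0.353), and without male 1, 774 genes were called.

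Whether a mutant effect differed between the sexes was tested directly, and edgeR called 0 genes in all 3 tests, with 1169 genes at an unadjusted p under 0.05 for C3, 448 for C3Gt of C3/C3 dams and 435 for C3Gt of heterozygous dams, where 765 are expected by chance. DESeq2 called 49 for C3 and 1 for C3Gt of C3/C3 dams. For C3 edgeR itself called 853 with only the groups compared and 65 with a replicate block. For the interferon response the difference between the sexes had a median of 0.27 (adjusted p = 0.00207) for C3, 0.12 (0.0392) for C3Gt of C3/C3 dams and 0.30 (7.47e-05) for C3Gt of heterozygous dams, with adjusted p of 0.666 or higher with an estimated correlation and 0 members adjusted over the list alone. For C3 the median turned to -0.22 (adjusted p = 0.323) with the decidual score as covariate. The call was lost for C3 without C3 female 2 (0.15) or male 2 (0.053), and for C3Gt of C3/C3 dams without wild-type male 1 (0.0556) or 2 (0.0651), wild-type female 2 (0.0926), C3Gt male 2 (0.188) or C3Gt female 2 (0.186). Without male 2 of heterozygous dams the last of the medians was 0.06 (adjusted p = 0.105), without female 4 it was 0.11, and without male 1 of heterozygous dams 157 genes were called.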

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

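The tests of a swap, of maternal tissue and of a wrong label for Mcm2, of a separate preparation of the wild-type libraries, of the decidual score in C3 placentas and of an estimated correlation between interferon genes were chosen after the result was seen.

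In the group of 4 females, C3Gt of heterozygous dams, 53 values were tested for a library far from the others, and chance marks about 1 in 20 of such values. Female 4 lay low in Mcm2 relative to Mcm3 to Mcm7, with a gap to the next library of 0.858 of the group's range, and high in Mamdc2 with 0.942, while female 3 lay low in Ptgs2 with 0.905, above the 95% critical value of Dixon's test. The 3 of 53 are about as many as chance marks.

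The effect of the mutant genotype differed between females and males for several lists, by camera on the interaction, with positive values where the female effect was higher. Every list named in this and the next 2 paragraphs had adjusted p of 0.513 or higher with an estimated correlation, and 0 genes passed on their own by edgeR, with 1169, 448 and 435 genes at an unadjusted p under 0.05 and 49, 1 and 0 called by DESeq2. For C3 placentas the medians on the log2 scale were 2.08 for uterine NK and T cell markers, 1.41 for decidual stroma markers, 0.309 for macrophage markers, 0.28 for immediate early genes, 0.268 for the interferon response, 0.262 for endothelial markers and 0.0937 for hypoxia and glycolysis. They were -2.81 for yolk sac endoderm markers, -1.19 for spongiotrophoblast markers, -0.504 for trophoblast giant cell markers, -0.463 for glycogen trophoblast markers, -0.375 for mitosis, -0.236 for DNA replication and -0.231 for cholesterol synthesis. Of these 6 turned with the decidual score as covariate: the medians were 0.40 for spongiotrophoblast markers, -0.31 for macrophage markers, -0.22 for the interferon response, -0.10 for decidual stroma markers and -0.0725 for endothelial markers, and the test of glycogen trophoblast markers turned. Single libraries ended calls of 7 further lists than the interferon response, given in the report: immediate early genes without C3 female 1 (adjusted p = 0.0757) or male 2 (0.0797). Macrophage markers were lost without wild-type female 2 (0.0606) or 3 (0.0737), wild-type male 2 (0.112), C3 female 1 (0.104) or 2 (0.15) or C3 male 2 (0.781). Glycogen trophoblast markers were lost without wild-type male 1 (0.063) or 2 (0.0581), wild-type female 2 (0.0517) or 3 (0.066), C3 male 1 (0.0779) or C3 female 2 (0.0532). Endothelial markers were lost without wild-type male 1 (0.331), wild-type female 1 (0.0618), C3 male 1 (0.0785) or C3 female 1 (0.1252), and yolk sac endoderm markers without wild-type male 1 (0.254) or wild-type female 1 (0.0743) or 2 (0.0999). Cholesterol synthesis was lost without wild-type male 1 (0.34), wild-type female 1 (0.0873) or 2 (0.17), C3 male 1 (0.479) or C3 female 2 (0.12), and hypoxia and glycolysis without wild-type female 1 (0.063), wild-type male 2 (0.112), C3 female 1 (0.0534) or C3 male 2 (0.0578).

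For C3Gt placentas of C3/C3 dams the medians were 1.25 for uterine NK and T cell markers, 0.793 for macrophage markers, 0.717 for neutrophil markers, 0.575 for erythroid genes, 0.289 for immediate early genes, 0.258 for NF-kB and inflammatory cytokines and 0.122 for the interferon response, and -0.518 for mitosis, -0.377 for cholesterol synthesis, -0.331 for the MCM helicase, -0.251 for the unfolded protein and integrated stress response and -0.23 for DNA replication. The MCM helicase lost its call without wild-type male 1 (adjusted p = 0.0703) or 2 (0.0729), wild-type female 2 (0.0799) or 3 (0.0665), C3Gt male 1 (0.254) or C3Gt female 2 (0.838). Neutrophil markers did without wild-type male 1 (0.0634) or 2 (0.0651), wild-type female 2 (0.0711) or 3 (0.119), C3Gt male 2 (0.272) or C3Gt female 2 (0.379). Erythroid genes did without wild-type female 2 (0.0799), wild-type male 2 (0.11), C3Gt female 1 (0.323) or C3Gt male 2 (0.366), and immediate early genes without wild-type male 2 (0.0519) or C3Gt male 2 (0.0597).

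For C3Gt placentas of heterozygous dams the medians were 0.874 for uterine NK and T cell markers, 0.299 for the interferon response, 0.26 for NF-kB and inflammatory cytokines, 0.208 for the IL-10 and prostaglandin pathway, 0.19 for mitosis and 0.184 for DNA replication, and -1.11 for spongiotrophoblast markers and -0.149 for Xist and X genes that escape inactivation. The value of 2.35 for Y-linked genes rests on stray fragments in females, where the 4 genes summed to 0 to 6.51 CPM, and says nothing of a mutant effect that differs by sex. Without C3Gt male 2 the calls of the interferon response (adjusted p = 0.105), spongiotrophoblast markers (0.89), uterine NK and T cell markers (0.756) and the IL-10 and prostaglandin pathway (0.0548) were lost, and the medians of mitosis (-0.44), DNA replication (-0.13) and spongiotrophoblast markers (0.21) turned. Without C3Gt male 1 the calls of NF-kB and inflammatory cytokines (0.199), the IL-10 and prostaglandin pathway (0.199) and Xist and X genes that escape inactivation (0.725) were lost. The IL-10 and prostaglandin pathway was also lost without wild-type male 1 (0.0703), wild-type female 2 (0.059) or 3 (0.0554) or C3Gt female 4 (0.141), and uterine NK and T cell markers without wild-type female 3 (0.0554) or C3Gt female 4 (0.0674). Xist and X genes that escape inactivation were lost without wild-type female 3 (0.066), wild-type male 2 (0.126) or C3Gt female 4 (0.0604).

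In the table that holds the 4 C3 placentas again, Syne1 had 403 and 522 fragments in the C3 males, where the table of males has 1 and 2. Both tables have 699 and 650 fragments in the C3 females.

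Many genes differed between wild-type and mutant placentas, 5186 of them between C3Gt females of heterozygous dams and wild-type females. Of 35 splits of these 7 libraries the real one gave most genes (5186, then 2379). Chance differences of litters, which labels omit, stay open. A trend with ribosomal RNA carried through the poly(A) selection may add to the difference. Within the mutant groups, the slope of genes on log2 Rn45s had a correlation of -0.1761 with the wild-type difference, inside the range of within-group permutations (-0.5337 to 0.5694, with 30 of 100 as low), so this trend was neither shown nor excluded. A separate preparation of the wild-type libraries, the genotype of the dam and that of the placenta cannot be told apart, because the lowest wild-type library had 1.379% Rn45s and the highest mutant 0.869%.

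Mcm2 split the libraries labelled Gt/+. The largest gap among the 10 ratios left 4 low libraries, the highest at 0.5242. If the allele lowers Mcm2 wherever it is present, swaps with libraries labelled without Gt are argued against, because each needs a low partner there and the lowest of those 9 had 0.7334 (SD of the 9, 0.053). Maternal tissue without the allele is argued against for heterozygous dams if their labels are right, since 0 of those 6 libraries came from a dam labelled without Gt. For C3/C3 dams it stays open: across their 4 libraries the ratio had a Pearson r of -0.8892 with the decidual score, with a 95% interval of -0.9977 to 0.4943. Wrong labels of single libraries stay open, as the 6 high libraries had ratios of 0.8117 or more and no second marker of the allele is counted. So does an allele that lowers Mcm2 in some placentas only, which was not tested.

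The interferon response was higher in female than in male mutants as a list, but 0 of its members were called, and for heterozygous dams adjusted p was 0.562 with an estimated correlation. In C3Gt placentas of heterozygous dams a share of decidual tissue is argued against as the whole cause, since the median was 0.2834 with the decidual score as covariate and 0.32 without. In C3 placentas it fell from 0.33 to -0.02967 with that covariate, so the share of decidua may account for the difference there. A single library stays open for heterozygous dams, with a lowest median of 0.1333, without male 2, and so does a chance shift of correlated genes, since with an estimated correlation the unadjusted p was 0.08035. A response to the sex of the embryo, which the design names, cannot be told apart from these with 2 males in the group.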

How the results depend on the processing

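The first set of alternatives was chosen before the data were examined; log2 Rn45s as covariate, the table of the C3 placentas and the sex comparisons without genes that differ between tables were chosen after seeing the data. RLE size factors kept all 160 list results and 768 of 776 gene results, and DESeq2 kept 696 of the genes, with 9 weaker and 71 newly past the threshold. Of the 160 list results 20 had not passed the threshold, and of the others 5 kept an adjusted p under 0.05 with an estimated correlation. The cause was not tested unless stated.

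Counts of called genes moved as follows. RLE gave 1 between C3Gt females of the 2 kinds of dam (0 in the report), and so did all 19 libraries in a single fit, and the fit without a count filter, which also gave 308 for C3 males against wild-type. With all 19 libraries the males against wild-type had 3106 genes for heterozygous dams, 3990 for C3Gt of C3/C3 dams and 2148 for C3; more residual degrees of freedom go with this fit. With only the groups compared, counts were 7907 for C3 females against wild-type, 5 for C3Gt against C3 females and 1 for C3Gt against C3 males. Against wild-type, males then had 714 for heterozygous dams, 3731 for C3Gt of C3/C3 dams and 2241 for C3. Between the sexes it gave 913 in C3, 1 in C3Gt of C3/C3 dams and 1 in C3Gt of heterozygous dams, and 853 for the C3 interaction. Autosomal genes only left 1, 1, 1 and 3 genes between the sexes, each time with the table-dependent Syne1. Without the genes that differ between tables these counts were 4, 5, 4 and 5, and Xist lost its call in wild-type (adjusted p = 0.0568) and in C3Gt of C3/C3 dams (0.0504). The table of the C3 placentas gave 911 genes between C3 females and males. DESeq2 gave 381 and 21 for the 2 comparisons among mutant females, 42 and 331 for those among mutant males, 2423 for males of heterozygous dams and 1600 for C3 males against wild-type. Between the sexes it gave 11 in wild-type, 208 in C3, 16 in C3Gt of C3/C3 dams and 14 in C3Gt of heterozygous dams, and 49 and 1 for the interactions of C3 and of C3Gt of C3/C3 dams.

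With the replicate number as a block (replicate block), counts were 26 and 17 for the comparisons among mutant females, 0 for males of heterozygous dams and 559 for C3Gt males of C3/C3 dams against wild-type, 385 between the sexes in C3 and 65 for the C3 interaction.

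With log2 Rn45s as covariate, which the groups nearly fix, counts were 0, 0 and 0 in females against wild-type, and in males 1 for heterozygous dams, 0 for C3Gt of C3/C3 dams and 1 for C3. Of gene results 330 lost their call, 30 turned and 87, called or not, stayed so. The list medians that turned were cholesterol synthesis in C3Gt males of C3/C3 dams (-0.40) and in C3 males mitosis (-0.89) and hypoxia and glycolysis (0.0014). The genes that turned were Bst2 (0.10) and Cxcl1 (0.012) in females of heterozygous dams. In C3Gt females of C3/C3 dams they were Dhcr24 (-0.46), Ldlr (-0.22), Tek (-0.69), Atf3 (0.21), Isg15 (0.18), Bst2 (0.24), Lyve1 (-0.83), Cenpe (-0.28), Anln (-0.14) and Vcam1 (-0.0386). In C3 females they were Dhcr24 (-0.14), Pola1 (-0.0507), Bst2 (0.21), Cenpe (-0.0337) and Cxcl1 (0.99). In C3Gt males of C3/C3 dams they were Dhcr24 (-0.0387), Tie1 (-0.56), Kdr (-0.28), Met (-0.33), Esx1 (0.27), Rn45s (0.0579), Hcn4 (-0.0512), Apaf1 (-0.21), Pgr (-1.41), Esr1 (-1.005), Sdf2l1 (0.39), Atf3 (0.25) and Creld2 (0.29).

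With the decidual score as covariate, counts were 2985 for females and 0 for males of heterozygous dams, 0 for C3Gt males of C3/C3 dams against wild-type, and 8 between C3Gt females of the 2 kinds of dam. Of list results 37 lost the call, 5 gained it, 14 turned and 104, called or not, stayed so. Those that turned between C3Gt and C3 males were uterine NK and T cell markers (-0.14), decidual stroma markers (-0.14) and cholesterol synthesis (-0.31). Between the sexes in C3 they were the interferon response (-0.0297), uterine NK and T cell markers (0.11, the test turning), decidual stroma markers (-0.31), spongiotrophoblast markers (0.34) and immediate early genes (-0.13). For the C3 interaction they were the interferon response (-0.22), macrophage markers (-0.31), decidual stroma markers (-0.10), spongiotrophoblast markers (0.40), glycogen trophoblast markers (-0.15, the test turning) and endothelial markers (-0.0725). Fcer1g (-0.0772) and Cd14 (-0.12) turned in females of heterozygous dams. The decidual stroma markers make up the score, so their own change follows from it.

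Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave these ranges of counts. Against wild-type, females of heterozygous dams had 3138 to 5484, C3Gt females of C3/C3 dams 3511 to 4105, C3 females 1477 to 3600, males of heterozygous dams 0 to 1772, C3Gt males of C3/C3 dams 0 to 1458 and C3 males 0 to 4. Among mutants the counts were 0 to 186 and 0 to 6 in females, and 0 to 350 and 0 to 6 in males. Between the sexes they were 5 to 6 in wild-type, 2 to 7 in C3, 2 to 8 in C3Gt of C3/C3 dams and 5 to 774 in C3Gt of heterozygous dams, and the interactions had 0 to 1, 0 to 1 and 0 to 157. The correlation of female with male fold changes ran from 0.27 to 0.47 for C3, 0.54 to 0.74 for C3Gt of C3/C3 dams and 0.36 to 0.73 for heterozygous dams; without the count filter it was 0.23, 0.41 and 0.31.

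Without some library the medians of 93 of the 140 called lists turned or moved by over 1.5 times. The 19 that turned had these ranges. For C3Gt against C3 females they were -0.70 to 0.0569 for the MCM helicase and -0.63 to 0.0742 for mitosis, and DNA replication turned in its test (-0.29 to -0.0259), the highest each time without C3Gt female 2. Without it DNA replication also turned against wild-type (-0.41 to 0.00198), and so did the MCM helicase between the sexes in C3Gt of C3/C3 dams (-0.68 to 0.000272). For C3Gt against C3 males yolk sac endoderm markers ran from -5.65 to 0.63, and for the C3 interaction macrophage markers from -0.0422, without C3 male 2, to 0.99. The following turned without male 2 of heterozygous dams. Against wild-type males DNA replication ran from -0.77 to 0.0389, and against C3Gt males of C3/C3 dams spongiotrophoblast markers from -0.20 to 1.73, DNA replication from -0.85 to 0.0248 and the MCM helicase from -1.32 to 0.0421. Between the sexes the ranges were -0.32 to 1.00 for the MCM helicase, -0.13 to 0.64 for DNA replication, -0.30 to 1.36 for mitosis, -0.15 to 0.42 for DNA damage signalling and repair, -1.64 to 0.34 for spongiotrophoblast markers and -0.26 to 0.0252 for the unfolded protein and integrated stress response. For the interaction of heterozygous dams they were -0.13 to 0.69 for DNA replication, -0.44 to 1.23 for mitosis and -1.77 to 0.21 for spongiotrophoblast markers.

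Depth of 14.8 to 23.5 M fragments limits genes of few fragments, since a gene at 0 can hold up to 3 fragments by counting error alone.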

Other observations

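The tests in this part were planned before the data were examined.

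Acsl6 had 0.066 to 0.36 CPM in the 5 wild-type libraries. C3Gt females of C3/C3 dams had 35.2 and 0.384 CPM and males 0.522 and 0.372. The other mutants had 9.57 to 48.1 CPM.

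Alleles carried along with a mutated gene could make its neighbours change more often. Within 10 Mb of Mcm4, on chromosome 16, 49.7% of genes (77 of 155) had an unadjusted p under 0.05 between C3 and wild-type females, against 44.3% elsewhere (6587 of 14855; one-sided Fisher exact p = 0.106). Within 10 Mb of Mcm2, on chromosome 6, the share was 10.5% (14 of 133) between C3Gt and C3 females of C3/C3 dams, against 9.09% elsewhere (1352 of 14877; one-sided Fisher exact p = 0.324). Neither p passed the threshold, and a p that misses it does not show equal shares, so such alleles were neither shown nor excluded.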
